A study of Mus musculus with 4 samples.

How the data were processed

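The data are 4 RNA sequencing libraries of laser-captured mouse molar mesenchyme at embryonic day 13.5, 1 for each combination of genotype (control or mutant) and molar (upper or lower). Per the labels' protocols, frozen heads were sectioned, total RNA of the captured tissue was extracted with an RNeasy Micro kit, cDNA was made with the NuGEN Ovation RNA-Seq v2 assay, and libraries were made with an Illumina Nextera kit. Reads were aligned with TopHat 1.4.1 and Bowtie 0.12.7 on the mouse genome build mm9, per the submitters' processing notes. The deposited tables have the layout of Cufflinks output, and the Cufflinks version, read length, strand setting and treatment of reads with several alignments were not given in the sources used here. cDNA amplification from small amounts of captured RNA and the sharing of reads between overlapping or near-identical transcripts could therefore affect single values.

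The authors' tables give FPKM (fragments per kilobase of transcript, scaled to mapped reads) for 28107 RefSeq transcripts, with gene symbol, locus, length and an estimation status, per the file headers. They also give the deposited coverage of each transcript, which was a constant multiple of FPKM within a library. The authors normalised FPKM to mapped reads, and the tables give no confidence limits of FPKM. Between 19 and 55 transcripts per library had a failed estimate and 294 per library had too little data, per the file headers. For Asph all 10 transcripts failed in both mutant libraries and were listed at 0.

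FPKM was summed over the transcripts of each of 22072 gene symbols. 43 symbols had transcripts on more than 1 chromosome. Coordinates are the range of a gene's loci in the deposited tables, on mm9 and counted from 1. Depth was estimated from coverage times length, which gave the bases aligned to transcripts. Single-read genes had a median of between 43.7 and 44.4 bases, taken over values from 25 to 60 bases on single-transcript genes longer than 1000 bases, and bases were divided by the mean of 44.2 to give approximate reads. Whole reads could not be recovered, so no test on counts was run. The ratio of coverage to FPKM gave between 13000000 and 14900000 approximate mapped reads per library. These figures cover counting error only, and amplified reads are not independent molecules.

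Differences were taken on log2(FPKM + 1), so the pseudocount was 1, among the 10502 genes with a mean of at least 1 FPKM over the 4 libraries. Within a molar, with 1 library per genotype, genes with an absolute log2 difference of at least 1 (2-fold) were counted without a test. Over both molars, limma 3.58.1 in R 4.3.3 was fitted with genotype and molar as additive terms and with an intensity trend in its empirical Bayes step, two-sided, with Benjamini-Hochberg adjustment at 0.05. The fit leaves 1 residual degree of freedom, which is the difference of the genotype effect between molars, and the prior added 5.77 degrees of freedom. Its p-values therefore rest on that disagreement between molars, taken mostly from genes of similar expression through the prior. They do not rest on the spread between embryos or between pools of a genotype. On simulated data for the genotype comparison, over 10502 genes, limma recovered 35.8% of genes changed by 0.585, 95.5% of those changed by 1 and 100% of those changed by 2 on the log2 scale. Of 172 calls there, 18 were of unchanged genes. The simulated noise was drawn separately for each library, with no effect shared by both molars of a genotype. These shares are therefore not the power of the real comparison.

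Gene lists were written before the data were examined, 26 in all, covering BMP, Wnt, FGF, hedgehog and retinoic acid signalling, odontogenic, osteogenic, cartilage and matrix genes, positional genes of the arches, proliferation and stress, and markers of other cell types. Older symbols were matched through the synonyms of RefSeq genes of GRCm38.p6, used for names only. For each list with at least 3 tested genes, the percentile of its median was taken among 10000 random lists of the same size drawn within 20 bins of mean FPKM, and is called outside where it fell outside the central 95%. In a check on 40 random lists of 20 genes in the lower molar, 3 were outside without a shift and 40 with a shift of 0.3. limma p-values were also adjusted over each list alone.

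Named genes followed a rule fixed before the data were examined. Bmp4 came first. Among genes with a mean of at least 2 FPKM and without a provisional, small RNA or pseudogene symbol, it took the 12 highest and 12 lowest in the mutant by the smaller of the differences in the 2 molars, and the 8 highest and 8 lowest in the lower molar in the same way. It also took up to 5 genes in each direction that differed at least 2-fold in opposite directions, of which there were none, up to 4 members of each list with a mean of at least 1 FPKM and the largest effect, and Msx1, Osr2, Dkk2, Pax9, Lef1, Inhba, Fgf3 and Runx2. Xist, a member of the list of sex-linked genes, was named in addition, after its values were seen.

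The alternatives tried were a pseudocount of 0.1 or 5, no filter or a mean of at least 5 FPKM, rescaling by the median ratio to the geometric mean, genes with an OK status in all libraries, no term for the other factor, no intensity trend, leaving out each library (with no term for the other factor, since 3 libraries leave no residual with both), and, chosen after seeing the data, leaving out genes whose longest transcript is under 0.3 kb. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.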

Results

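Gene expression was measured by RNA sequencing in mouse molar tooth mesenchyme at embryonic day 13.5, taken from frozen sections by laser capture microdissection. The mutant (Bmp4f/f;Wnt1Cre) lacks the signalling ligand Bmp4 in cells that express Wnt1-Cre, a Cre driver active in the neural crest, which gives rise to tooth mesenchyme. The control carried 1 floxed and 1 unmodified Bmp4 allele (Bmp4f/+). Its label names no Wnt1-Cre, so an effect of the Cre transgene itself cannot be told apart from the loss of Bmp4. Upper (maxillary) and lower (mandibular) molars were collected apart, which gave 4 groups with 1 library each. Each library was a pool, made from 3 pairs of control and mutant samples according to the series description. The depth behind the deposited values was about 4840000 reads on annotated transcripts in the control upper molar, 4820000 in the control lower molar, 5550000 in the mutant upper molar and 5000000 in the mutant lower molar. A transcript of 2 kb with 3 reads would have had between 0.101 and 0.115 FPKM. Between 10444 and 10463 genes reached 1 FPKM in each library, and 10502 of 22072 listed genes had a mean of at least 1 FPKM and were tested. Values are FPKM summed per gene, and differences are on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes. Within a molar there was no replicate of a genotype, so a difference there carries no p-value. The p-values over both molars set a difference against a disagreement between molars or genotypes. limma drew this disagreement mostly from genes of similar expression, with 5.77 prior degrees of freedom against 1 residual degree of freedom. The p-values do not measure the spread between embryos or between pools of a genotype. The labels do not say whether both molars of a genotype came from the same embryos, and an effect common to both counts as genotype.

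The gene targeted in the mutant was examined first. Bmp4 (chromosome 14, 47003196 to 47010274, mm9, 1 RefSeq transcript) had 24.8 FPKM in the control upper molar and 27.2 FPKM in the control lower molar. It had 4.75 FPKM in the mutant upper molar and 4.90 FPKM in the mutant lower molar, which was 19.2% and 18.0% of the control value. The transcript was read with about 646 reads in the control upper molar and about 138 reads in the mutant lower molar. Over both molars Bmp4 fell by 2.21 ± 0.11 (log2, SE, limma adjusted p = 0.0008, 2 libraries per genotype). limma no longer called Bmp4 when either control library was left out, or without a filter on low values. The part of the gene removed by Cre was not given in the sources used here, so the remaining FPKM can include reads from parts that were not removed.

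The first comparison asked which genes of the molar mesenchyme differed between mutant and control in both jaws. Among genes that fell with Bmp4 were several known to respond to BMP signalling. Msx2, a homeobox transcription factor (chromosome 13, 53562250 to 53568149), had 3.77 and 3.10 FPKM in the control upper and lower molar and 0.783 and 0.399 FPKM in the mutant, and fell by 1.49 ± 0.14 (log2, SE, limma adjusted p = 0.015). Id3, an inhibitor of basic helix-loop-helix factors, was at 81.2 and 60.1 FPKM in the controls and 42.2 and 21.4 FPKM in the mutants. Smad9, an intracellular transducer of BMP signals, was at 5.80 and 4.35 FPKM in the controls and 2.42 and 1.15 FPKM in the mutants. Genes that rose included the zinc finger transcription factor Osr1 (chromosome 12, 9581248 to 9588306), at 6.81 and 22.6 FPKM in the controls and 20.9 and 50.1 FPKM in the mutants. Osr1 rose by 1.30 ± 0.13 and its paralog Osr2 rose by 0.78 ± 0.11 (log2, SE, limma adjusted p = 0.015 and 0.039).

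limma called 36 genes higher and 48 genes lower in the mutant at an adjusted p under 0.05, of 10502 genes tested, with Asph, which was not measured in the mutant, among the 48. Of these 84 genes, 13 had a longest transcript under 0.3 kb, as had 5 of the 14 called after rescaling. An unadjusted limma p under 0.05 for genotype was reached by 1386 of the 10502 genes. The 12 named genes with the largest decrease shared by both molars were picked by these same differences, so passing the test adds no separate support. Of them, 11 were measured in all libraries, and limma called all 11 lower. Beside Bmp4, Msx2 and Smad9 these were Spock1 (a proteoglycan of the extracellular matrix), Rgs5 (a regulator of G protein signalling found in pericytes), Cthrc1 (a secreted collagen triple helix protein), Hey1 (a transcriptional repressor downstream of Notch), Sox9 (a transcription factor of cartilage formation), Mical2 (an actin-oxidising enzyme), Ptch1 (the hedgehog receptor) and Pgm2l1 (an enzyme of glucose 1,6-bisphosphate synthesis). Spock1 fell by 1.55 ± 0.11, Rgs5 by 1.51 ± 0.13, Hey1 by 1.62 ± 0.20 and Sox9 by 1.18 ± 0.11 in log2 units (SE, limma adjusted p = 0.0054, 0.011, 0.028 and 0.015). The remaining gene of the 12, Asph, was listed at 0 in both mutant libraries with a failed estimate for all 10 of its transcripts and is not counted as measured there. Of the 12 named genes with the largest shared increase, picked in the same way, limma called 11 higher. These were Gdf7 (a ligand of the BMP family), Lmcd1, C1qtnf7, Osr1, Fgf18 (a fibroblast growth factor), Crabp2 (a retinoic acid binding protein), Cntn4 (a neural adhesion molecule), Nbl1 (a secreted BMP antagonist), Atp10d, Chodl and Agtr2 (the type 2 angiotensin II receptor). Gdf7 rose by 1.72 ± 0.19, C1qtnf7 by 1.39 ± 0.12, Fgf18 by 1.11 ± 0.11 and Crabp2 by 1.41 ± 0.20 in log2 units (SE, limma adjusted p = 0.021, 0.011, 0.017 and 0.037). The other member, Nefl, a neurofilament gene, was higher in the mutant by 2.27 in the upper and 1.03 in the lower molar and did not pass the test (limma adjusted p = 0.057).

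**Figure D1:**
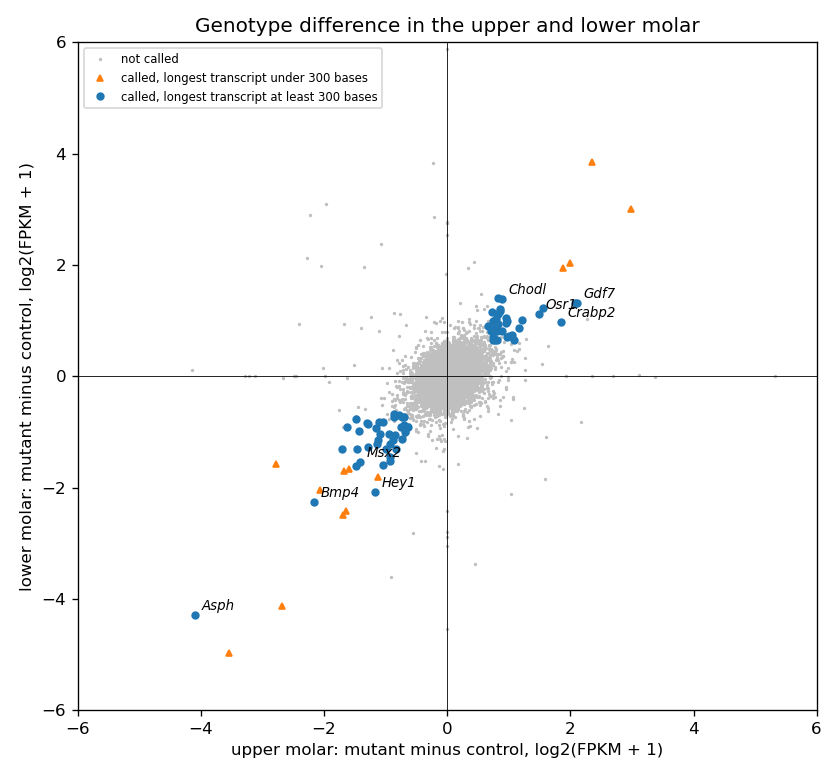
Mutant minus control difference of 10502 tested genes in the upper molar (x axis) and lower molar (y axis) on the log2(FPKM + 1) scale, with 1 library per group and with genes called by limma over both molars as blue circles, or orange triangles where the longest transcript is under 0.3 kb. Bmp4 lies at -2.16 and -2.26, and the zeros of Asph in the mutant are failed estimates.

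The number of calls moved with the processing: limma called 14 genes after rescaling by median ratios, 38 without an intensity trend, 7 without a term for the molar, 146 at a mean FPKM of at least 5, 140 without transcripts under 0.3 kb, and 0 without a filter on low values, where 1398 genes had an unadjusted p under 0.05. Leaving out 1 library, which also leaves no term for the molar, gave 5 calls without the control upper, 8 without the control lower, 18 without the mutant upper and 10 without the mutant lower library. Of the measured genes named here for a shared difference, C1qtnf7, Osr1, Fgf18, Bmp4, Spock1, Rgs5, Cthrc1 and Sox9 were still called after rescaling, only Bmp4 and Spock1 without a term for the molar or without the mutant lower library, Bmp4, Spock1 and Hey1 without the mutant upper library, and none without either control library or without a filter.

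Single genes long studied in the early molar were examined by name. Msx1, a homeobox gene of tooth mesenchyme, was lower in the mutant by 0.15 in the upper and 0.36 in the lower molar. It had 135 and 98.4 FPKM in the mutants, and it overlaps the antisense gene Msx1as. Pax9 was higher in the mutant, at 74.9 and 108 FPKM against 57.4 and 84.9 FPKM. Lef1 was lower by 0.37 in the upper and 0.57 in the lower molar, and Runx2 was lower by 0.64 and 0.62. Dkk2, a secreted Wnt modulator, was higher at 4.41 and 19.7 FPKM against 2.61 and 10.2 FPKM. Of these 5 genes none passed the test (limma adjusted p = 0.38 for Msx1, 0.21 for Pax9, 0.16 for Lef1, 0.056 for Runx2 and 0.061 for Dkk2). Inhba was 0.26 higher in the mutant in the upper molar and 0.35 lower in the lower molar. Fgf3 was at or under 0.273 FPKM, 5 reads or fewer, and a difference was not detectable at this depth.

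**Figure D2:**
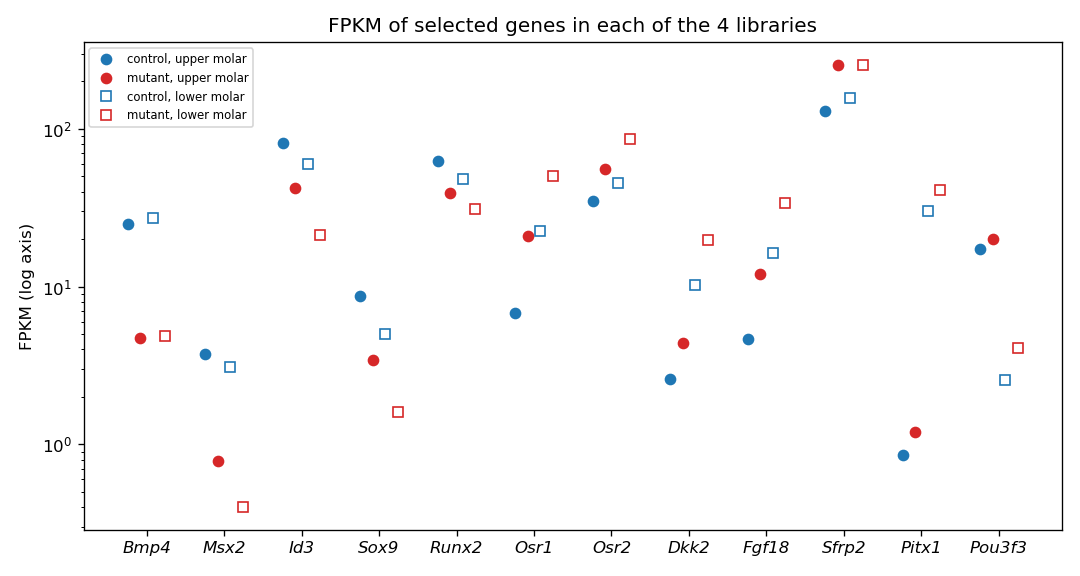
FPKM on a log axis for 12 genes with 1 point per library, blue for control and red for mutant, filled circles for the upper and open squares for the lower molar. Bmp4, Msx2, Id3, Sox9 and Runx2 have lower values in both mutant libraries, Osr1, Osr2, Dkk2, Fgf18 and Sfrp2 have higher values in both, and Pitx1 and Pou3f3 separate the molars.

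The genotype comparison was then made for gene lists written down before the data were examined. In BMP response genes, 13 of the 14 tested members were lower in the mutant in both molars. The list median was -0.49 in the upper and -0.46 in the lower molar, at percentiles 0.00 and 0.00 of random lists matched on expression. limma called 4 of the 14 lower (Hey1, Msx2, Id3 and Smad9) and 8 lower when adjusted over the list alone, and none of these 4 calls remained after rescaling. BMP ligands, receptors and extracellular modulators had a median of 0.03 in the upper molar and -0.35 in the lower molar (percentiles 58.7 and 0.00). In this list limma called 1 of 17 genes lower (Bmp3, from 5.17 and 3.93 to 2.82 and 1.47 FPKM), and 3 lower when adjusted over the list alone. Without regard to the test, 8 of the 17 were lower and 5 higher in the mutant in both molars. Chrdl1 was lower in both molars and Bmp7 was higher, neither past the test.

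Hedgehog pathway and response genes had a median of -0.34 in the upper molar (percentile 0.00) and -0.20 in the lower molar (percentile 5.76). Ptch1 fell from 76.0 and 49.7 FPKM to 27.5 and 24.8 FPKM, and Gli1, a transcription factor and target of the pathway, fell from 23.8 and 22.9 FPKM to 14.2 and 11.6 FPKM. limma called these 2 of 9 genes lower, and 1 higher and 4 lower when adjusted over the list alone. In osteogenic genes the medians were -0.57 and -0.43 (percentiles 0.00 and 0.00). limma called 1 of 8 tested genes lower, against 5 lower when adjusted over the list alone. Sp7 and Alpl, both of the osteoblast lineage, were lower by 1.76 and 0.89 in the upper and by 0.61 and 0.44 in the lower molar without passing the test. Cartilage genes had medians of -0.46 and -0.31 (percentiles 0.02 and 1.57). Sox9 was the 1 called gene among 5, with 2 lower when adjusted over the list alone.

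Among odontogenic transcription factors, limma called 2 of 28 genes higher (Osr1 and Osr2) and 2 lower (Msx2 and Gli1), against 5 and 7 when adjusted over the list alone. Without regard to the test, 9 of the 28 were higher and 12 lower in the mutant in both molars. The medians were 0.02 in the upper molar and -0.19 in the lower molar (percentiles 27.6 and 1.08). Secreted Wnt antagonists went both ways. Sfrp2 rose from 129 and 157 FPKM to 254 and 256 FPKM, while Sostdc1, which antagonises Wnt and BMP signals, fell from 117 and 122 FPKM to 74.4 and 63.8 FPKM (limma adjusted p = 0.033 and 0.040, 1 gene each way of 8, and 4 higher and 2 lower adjusted over the list alone). The medians were 0.13 and 0.24 (percentiles 83.4 and 99.8), and Dkk3 was lower in both molars without passing the test. Without a filter on low values the lower molar median of this list was 0.00 and inside the central range. Wnt/beta-catenin target genes had medians of 0.01 and -0.10 (percentiles 45.7 and 28.5). In this list limma called 3 of 14 genes lower (Bmp4 itself, Lgr6 and Tcf7), against 2 higher and 5 lower when adjusted over the list alone. Without regard to the test, 6 of the 14 were lower and 5 higher in the mutant in both molars.

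FGF ligands and FGF response genes had a median of 0.38 in the upper molar (above all matched random lists) and 0.03 in the lower molar (percentile 91.2). Fgf18 and Dusp6, a phosphatase that limits ERK signalling, rose (limma adjusted p = 0.017 and 0.048, 2 of 15 genes, and 4 higher and 3 lower adjusted over the list alone). Spry1 was higher by 0.87 and 0.44 and Etv4 lower by 0.43 and 0.80, neither past the test. In the retinoic acid pathway Crabp2 rose (limma adjusted p = 0.037), and limma called 2 of 10 genes higher, against 3 higher and 2 lower when adjusted over the list alone. The medians were 0.17 and 0.02 (percentiles 97.4 and 87.8). Aldh1a2, which makes retinoic acid, was lower by 0.36 in the upper and 1.52 in the lower molar, and Crabp1 was higher by 0.20 and 1.32. Neither passed the test, and the difference between molars was not tested. Mesenchymal matrix and condensation genes had medians of 0.09 and 0.13 (percentiles 77.6 and 99.9). limma called 0 of 17, with 8 at an unadjusted p under 0.05, and 3 higher and 1 lower when adjusted over the list alone. Postn and Dcn were higher and Fbn1 and Tnc lower in the mutant in both molars.

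Proliferation genes were lower in the mutant lower molar for all 28 members, with a median of -0.42 (percentile 0.00). In the upper molar 22 of 28 were lower and the median was -0.11 (percentile 0.03). Mki67 had 64.7 and 64.0 FPKM in the controls and 47.8 and 41.2 FPKM in the mutant upper and lower molar. Rrm2, a ribonucleotide reductase subunit, was lower by 0.16 in the upper and 0.69 in the lower molar, Tpx2 by 0.27 and 0.58, and the mitotic kinase Plk1 by 0.22 and 0.61. limma called 0 of the 28 over both molars, with 10 at an unadjusted p under 0.05, and 0 when adjusted over the list alone. Cell cycle inhibitors and p53 targets had medians of 0.05 and 0.08 (percentiles 64.5 and 91.3). Hypoxia and glycolysis genes had medians of 0.34 and 0.12 (percentiles 99.98 and 97.4). Immediate early and heat shock genes had medians of 0.15 and -0.08 (percentiles 94.0 and 32.6), and housekeeping genes 0.02 and -0.06 (percentiles 29.5 and 58.0). In these 4 lists limma called 0 genes, also when adjusted over the list alone, with 0 cell cycle inhibitors or p53 targets, 5 hypoxia and glycolysis genes, 1 immediate early or heat shock gene and 2 housekeeping genes at an unadjusted p under 0.05.

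**Figure D3:**
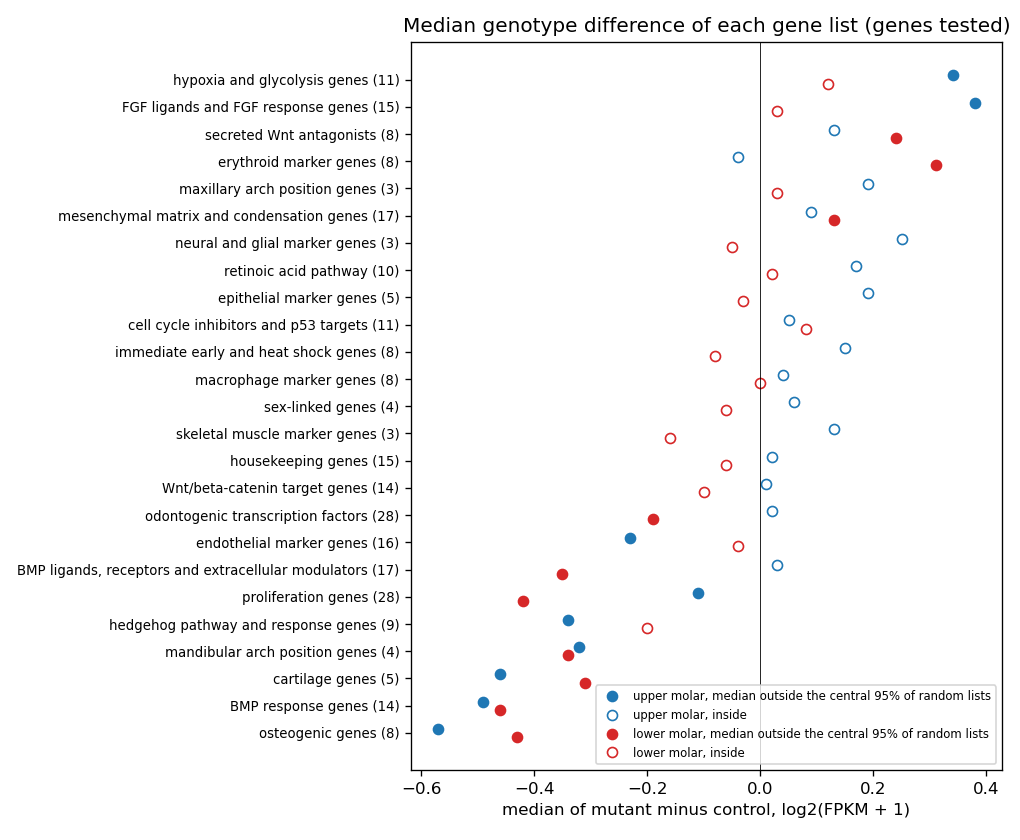
Median mutant minus control difference on the log2(FPKM + 1) scale for 25 gene lists, with the number of tested genes after each name, blue for the upper and red for the lower molar, filled where the median lay outside the central 95% of 10000 random lists matched on expression. The medians of osteogenic genes were -0.57 and -0.43, and those of BMP response genes -0.49 and -0.46.

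Of the 25 lists with at least 3 tested genes, 9 lay outside the central 95% of random lists in the upper and 10 in the lower molar, where 1.25 would be outside by chance for unrelated genes, and 5 lay outside in both in the same direction. The lists share genes and their members vary together, so these percentiles describe the 4 libraries and are not tests. Without a filter on low values the medians of cartilage and mandibular arch position genes in the upper molar were -0.08 and -0.14 and no longer outside. In the lower molar odontogenic transcription factors, secreted Wnt antagonists (0.00) and mandibular arch position genes (-0.18) were no longer outside. Hedgehog genes in the lower and Wnt/beta-catenin target genes in the upper molar came to lie outside. The medians of osteogenic genes and of FGF ligands and FGF response genes in the upper molar were -0.18 and 0.11 and still outside. Of the list members that limma called for genotype, Bmp4, Osr1, Fgf18 and Sox9 were still called after rescaling and the others were not.

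Markers of other cell types that a capture could include were compared between genotypes. Endothelial marker genes were lower in the mutant upper molar for all 16 members, with a median of -0.23 (percentile 0.02), and had a median of -0.04 in the lower molar, inside the central range. Cdh5 was at 16.3 FPKM in the control and 10.3 FPKM in the mutant upper molar. Erythroid marker genes had medians of -0.04 and 0.31 (percentiles 10.3 and 99.97), and the 7 listed globin genes together made up between 0.587% and 0.733% of the FPKM sum of a library. Epithelial marker genes had medians of 0.19 and -0.03 (percentiles 91.2 and 48.2), and Krt14 lay between 1.58 and 3.91 FPKM. Macrophage marker genes had medians of 0.04 and 0.00, skeletal muscle marker genes 0.13 and -0.16, and neural and glial marker genes 0.25 and -0.05, all inside the central range. Sex-linked genes had medians of 0.06 and -0.06. Xist was at or under 0.0275 FPKM and the Y-linked gene Ddx3y between 5.02 and 5.62 FPKM in every library. limma called 0 genes in these lists, with 2 endothelial, 2 neural and glial, 1 epithelial and 1 macrophage marker gene at an unadjusted p under 0.05, and only the neural and glial list had calls when adjusted over the list alone, 1 higher and 1 lower. Mitochondrially encoded genes had no member among the listed transcripts.

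The genotype difference was also counted within each molar. In the upper molar 44 genes were at least 2-fold higher and 62 at least 2-fold lower in the mutant. In the lower molar 50 were higher and 65 lower. In both molars 10 genes were higher and 21 lower, where independent lists of these sizes would share 0.21 and 0.38 genes, and 10 genes went in opposite directions against 0.57. Asph, not measured in the mutant, is among the 21, and among genes with an OK status in all libraries 10 were higher and 18 lower in both. Across the 10502 genes, which are not independent replicates, the differences in the upper and lower molar correlated with Pearson r = 0.33 and Spearman rho = 0.31. All 10 genes that went in opposite directions had transcripts under 0.3 kb, and none met the rule for named genes. The counts depended on the pseudocount and the filter: with a pseudocount of 5 the shared genes were 2 and 6, with a pseudocount of 0.1 they were 27 and 44, at a mean FPKM of at least 5 they were 6 and 8, and without transcripts under 0.3 kb they were 6 and 12. Of the 31 shared genes, 13 had transcripts under 0.3 kb, with a median of 2.08 approximate reads over all 23 such short genes that differed 2-fold in both molars. Whether any gene responded differently to the mutation in the 2 molars could not be tested with 1 library in each cell of the design.

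The second comparison asked which genes distinguished lower from upper molar mesenchyme in both genotypes. Pitx1, a homeobox gene of the mandibular arch (chromosome 13, 55926415 to 55932786), was at 30.2 and 41.3 FPKM in the control and mutant lower molar and at 0.862 and 1.20 FPKM in the upper molar. It was higher in the lower molar by 4.16 ± 0.11 (log2, SE, limma adjusted p = 4.9e-05). The distal-less genes Dlx5 and Dlx6, which specify mandibular identity, were also higher in the lower molar (limma adjusted p = 0.0035 for both). Dlx5 was at 39.2 and 28.9 FPKM against 14.6 and 10.1 FPKM in the upper molar, and Dlx6 was higher by 1.58 ± 0.12 (log2, SE). Pou3f3, a POU-domain transcription factor (chromosome 1, 42753991 to 42757054), was higher in the upper molar, at 17.4 FPKM against 2.56 FPKM in the lower molar of the control, with 4.09 FPKM in the lower molar of the mutant, a lower minus upper difference of -2.21 ± 0.12 (log2, SE, limma adjusted p = 0.0016).

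limma called 41 genes higher and 35 lower in the lower molar. Of these 76 genes, 7 had a longest transcript under 0.3 kb. An unadjusted limma p under 0.05 for the molar was reached by 1075 of the 10502 genes. The 8 named genes with the largest shared excess in the lower molar were picked by these same differences, so passing the test adds no separate support. All 8 passed: Pitx1, Lrrn1 (a leucine-rich repeat neuronal protein), the chemokine Cxcl14, Dkk2, Dlx6, Fgf18, the hyaluronan receptor Cd44 and Dlx5. Lrrn1 was at 17.1 and 38.1 FPKM in the lower and 1.99 and 4.30 FPKM in the upper molar. Fgf18 was at 16.4 and 34.0 FPKM against 4.67 and 12.1 FPKM. Genes with the largest shared excess in the upper molar, picked in the same way, passed as well. Beside Pou3f3 they included Cbln1, Cited1 (a transcriptional coactivator), Pla2g7 (the platelet-activating factor acetylhydrolase), Crym, Gng3 and Igfbp5 (a binding protein of insulin-like growth factors). Cited1 was at 24.6 and 25.2 FPKM in the upper and 7.55 and 6.59 FPKM in the lower molar. Pla2g7 was at 12.8 and 4.04 FPKM in the upper and 1.14 and 0.465 FPKM in the lower molar. Dlx6 overlaps the antisense genes Dlx6as and Dlx6os1, Gng3 overlaps Bscl2, and no source used here says that strand was kept.

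Mandibular arch position genes had a median lower minus upper difference of 1.5 in the controls and 1.48 in the mutants, above all matched random lists in both, and 0.46 and 0.96 without a filter on low values. limma called 3 of 4 higher in the lower molar and 3 when adjusted over the list alone. The other member, Dlx3, was lower in the mutant, at 3.00 and 2.11 FPKM in the controls and 0.452 and 0.265 FPKM in the mutants (limma adjusted p for genotype = 0.024). Between genotypes the mandibular list had medians of -0.32 and -0.34 (percentiles 0.40 and 1.09), with 1 gene called lower, and 1 higher and 2 lower adjusted over the list alone. Maxillary arch position genes had medians of -0.26 in the controls and -0.78 in the mutants (percentiles 3.75 and 0.05). limma called 1 of 3 (Pou3f3), and 2 were lower when adjusted over the list alone. Irx5 was higher in the upper molar in both genotypes and Meis2 differed by -0.16 and 0.16. Between genotypes the maxillary list had medians of 0.19 and 0.03 (percentiles 86.8 and 66.6).

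At a 2-fold threshold, 19 genes were higher and 23 lower in the lower molar in both genotypes, where independent lists would share 0.31 and 0.34 genes. Another 8 genes went in opposite directions in the 2 genotypes, against 0.65. Across the 10502 genes the molar differences in control and mutant correlated with Pearson r = 0.3 and Spearman rho = 0.2. limma called 46 genes for the molar after rescaling, 12 without a term for genotype, 127 at a mean FPKM of at least 5, 139 without transcripts under 0.3 kb, and 0 without a filter, where 1225 had an unadjusted p under 0.05. Leaving out 1 library gave 14 calls without the control upper, 3 without the control lower, 21 without the mutant upper and 0 without the mutant lower library (407 at an unadjusted p under 0.05), and of the genes named here for a shared excess in a molar Pitx1 was called in the first 3 of these fits, Pou3f3 and Cited1 without either upper library, Pla2g7 without the mutant upper library and none of the others. Without a term for genotype the calls of Lrrn1, Cxcl14, Dkk2, Fgf18, Dlx5, Pla2g7, Crym and Igfbp5 ended, and that of Igfbp5 ended after rescaling. The labels do not say whether upper and lower molars came from the same embryos.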

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

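The comparison of opposite directions in the 2 molars at a threshold of 0.25, and the tests in this part, were chosen after the data were seen, except the test with lists matched on transcript length. Bootstrap intervals in this part resampled genes within the 4 libraries. They do not measure the spread between embryos or between pools of a genotype. Of the named genes, 3 moved in opposite directions in the 2 molars by at least 0.25 on the log2 scale, and the difference between molars was not tested for any of them. Inhba, which encodes an activin subunit, was higher in the mutant by 0.26 in the upper molar and had a difference of -0.35 in the lower molar. Egr1, an immediate early gene, had differences of 1.07 and -0.41. Myl4, a myosin light chain gene, had differences of 1.04 and -0.78, on between 0.624 and 2.33 FPKM.

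Proliferation genes were lower in the mutant lower molar, with a median of -0.42 over 28 genes against -0.11 in the upper molar. The tables argue against the scaling of the deposited FPKM as the whole cause, since a wrong scale moves every gene alike. The other 10474 tested genes had a median of -0.05 (95% bootstrap interval from -0.05 to -0.04). The tables also argue against a bias by transcript length. The median of the proliferation genes lay at percentile 0.0 of random lists matched on length and expression. The list already lay at percentile 0.00 of lists matched on expression alone, so the expression part of the match adds no separate support. Dilution of the tooth mesenchyme by other cells cannot be told apart: odontogenic transcription factors had a median of -0.19 (95% bootstrap interval -0.31 to 0.10), which meets the interval of the proliferation genes at -0.31 (-0.52 to -0.31). Erythroid marker genes were higher in the same library, with globin genes at 0.733% of the FPKM sum against 0.604% in the control lower molar. In that molar the epithelial, endothelial, macrophage, skeletal muscle, and neural and glial lists had medians of -0.03, -0.04, 0.00, -0.16 and -0.05. All of these lay inside the central range. Surrounding mesenchyme had no list of its own. An effect of the mutation on proliferation in the lower molar stays open and untested, with 1 pool per group.

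The 48 genes that limma called lower in the mutant had a median difference of -1.14 (95% bootstrap interval -1.29 to -1.06) over both molars, with Asph, which was not measured in the mutant, among them. They were picked for low values in the same libraries, so a gap to genes not picked this way was bound to appear. The comparisons that follow therefore cannot decide between causes. A smaller share of tooth mesenchyme in the mutant captures would lower tooth mesenchyme genes. The odontogenic transcription factors, of which Msx2 and Gli1 are among the 48, had a median of -0.07 (95% bootstrap interval -0.27 to 0.13). A wrong scale of the deposited FPKM moves every gene alike. The other 10454 genes had a median of -0.01 (95% bootstrap interval from -0.02 to -0.01), so they showed no common shift of the size seen in the 48. Rescaling by median ratios moved the effects too little to test the scale, with a median of -1.14 and a median SE of 0.13 against 0.14. It left 8 of the 48 called, with prior degrees of freedom of limma of 4.39 in place of 5.77. The loss of Bmp4 stays open as a hypothesis for these genes, alongside the Cre transgene and differences between pools, which the design cannot separate from genotype.

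The 10 genes that were 2-fold different in opposite directions in the molars all had transcripts under 0.3 kb. Counting noise on short transcripts is a candidate explanation. Of 23 such short genes that were 2-fold different in both molars, 56.5% went the same way (exact 95% interval 34.5% to 76.8%), on a median of 2.08 approximate reads per gene. No biological explanation was tested for the short genes.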

How the results depend on the processing

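Leaving out transcripts under 0.3 kb, and every alternative for the medians between molars and for genes going in opposite directions, were chosen after seeing the data. The planned count of genes with FPKM intervals that do not overlap was not run, because the tables give no confidence limits. Of the alternative values of lists, counts and correlations, 272 stayed on their side of the threshold or within 1.5 times, 54 moved by more or changed sign, 9 newly passed their threshold and 7 no longer passed it. The correlation of the genotype difference between molars stayed within 1.5 times of its reported value under its 5 alternatives, between 0.26 and 0.46.

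With a pseudocount of 0.1, genes 2-fold higher and lower in the mutant were 118 and 131 in the lower molar, 112 and 111 in the upper molar and 27 and 44 in both, with 23 in opposite directions, and 39 and 50 were higher and lower in the lower molar in both genotypes. With a pseudocount of 5 these were 13 and 20, 14 and 17, 2 and 6, 0, and 5 and 9. At a mean FPKM of at least 5 they were 19 and 26, 19 and 16, 6 and 8, 1, and 10 and 10, where fewer genes were tested. Without a filter 79 genes were higher in the mutant lower molar. Without transcripts under 0.3 kb, 27 were higher and 43 lower in the lower molar, 33 were lower in the upper molar, 6 and 12 were higher and lower in both, and 0 went in opposite directions.

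limma's genotype calls, 84 as reported, were 146 at a mean FPKM of at least 5 (48 shared with the 84), 140 without short transcripts (71 shared), 38 without a trend (38 shared), 14 after rescaling (14 shared), 7 without a term for the molar (7 shared) and 0 without a filter (1398 at an unadjusted p under 0.05). Leaving out 1 library gave between 5 (without the control upper library) and 18 (without the mutant upper library). The molar calls, 76 as reported, were 127 at a mean FPKM of at least 5, 139 without short transcripts, 46 after rescaling, 12 without a term for genotype and 0 without a filter (1225 at an unadjusted p under 0.05). Leaving out 1 library gave between 0 (without the mutant lower library, 407 at an unadjusted p under 0.05) and 21 (without the mutant upper library). Those fits have no term for the other factor, and the lone library of a group was assumed to vary like the others. Of the 24 genes named for a shared genotype difference, limma called 23 as reported, Asph included, and 9 after rescaling. Without a term for the molar 3 of the 24 were called, Asph, Bmp4 and Spock1, and without either control library only Asph. The genotype difference of Lrrn1, 0.97 as reported, lay between -0.48 and 2.41 when 1 library was left out. It reversed to -0.33 without the control upper and -0.48 without the mutant lower library, in fits with no term for the molar, between which Lrrn1 differs by 2.74.

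Medians of lists crossed the percentile limits in some settings. At a mean FPKM of at least 5, BMP ligands, receptors and extracellular modulators (-0.21) and odontogenic transcription factors (-0.16) in the lower molar were inside, while Wnt/beta-catenin target genes in the upper molar (0.17) and FGF (0.13) and retinoic acid genes (0.12) in the lower molar were outside, and the mandibular and maxillary lists had too few genes for a value. Without a filter, odontogenic transcription factors (-0.15), secreted Wnt antagonists (0.00) and mandibular arch position genes (-0.18) in the lower molar and cartilage (-0.08) and mandibular genes (-0.14) in the upper molar were inside. In the same setting hedgehog genes in the lower molar (-0.24) and the molar difference of maxillary genes in controls (-0.28) were outside, as were Wnt/beta-catenin target genes in the upper molar (-0.14, a change of sign). A pseudocount of 5 placed hedgehog (-0.18) and hypoxia and glycolysis genes (0.10) in the lower molar outside, rescaling placed the latter outside (0.18), and a pseudocount of 0.1 placed maxillary genes in controls outside (-0.49). Other medians of at least 0.2 in size moved by over 1.5 times without crossing the limits. Without a filter these were, in the upper molar, osteogenic genes (-0.18), FGF genes (0.11) and neural and glial marker genes (-0.06, a change of sign), and in the lower molar cartilage genes (-0.11) and BMP ligands (-0.19), with molar differences of 0.46 and 0.96 for mandibular genes in controls and mutants and -0.48 for maxillary genes in mutants. A pseudocount of 5 gave BMP response genes -0.28 in both molars, BMP ligands -0.14 and erythroid marker genes 0.19 in the lower molar, FGF genes 0.21, cartilage genes -0.17 and endothelial marker genes -0.12 in the upper molar, and molar differences of 0.96 for mandibular genes in mutants and -0.09 and -0.27 for maxillary genes in controls and mutants. A pseudocount of 0.1 gave BMP response genes -0.73 in the lower molar, cartilage genes -0.75 and -0.58 in the upper and lower molar, and maxillary genes -1.39 in mutants. A larger pseudocount shrinks every difference by construction. Apart from this and the smaller number of genes tested, the cause of these changes was not tested. Depth limited genes near 0.1 FPKM, where a 2 kb transcript had about 3 reads.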

Other observations

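Gene lists fixed for the genotype comparison also differed between the molars, a comparison chosen after the data were seen. Osteogenic genes had a lower minus upper median of 0.51 in the controls and 0.64 in the mutants, and Dlx5, which is also a mandibular arch gene, is among them. Secreted Wnt antagonists were higher in the lower molar, with medians of 0.41 and 0.32, as were mesenchymal matrix and condensation genes, with 0.23 and 0.29. Cartilage genes had medians of -0.60 and -0.40, BMP response genes -0.21 and -0.36, and odontogenic transcription factors -0.18 and -0.35. All of these lay outside the central 95% of matched random lists in both genotypes, and each median kept its sign after rescaling. Over all genes limma called 3 Wnt antagonists, 1 osteogenic gene and 1 matrix gene higher in the lower molar and 1 cartilage gene lower. Adjusted over the list alone these were 4 higher and 1 lower, 4 higher and 1 lower, 9 higher and 2 lower, and 1 higher and 3 lower. Of the odontogenic transcription factors limma called 3 higher and 0 lower in the lower molar, against the sign of their median, and 6 higher and 13 lower when adjusted over the list alone. Of the BMP response genes limma called 0, with 6 at an unadjusted p under 0.05, and 5 lower when adjusted over the list alone.

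Further gene families were examined after the data were seen. Protocadherin gamma genes had medians of -0.12 in the upper and 0.04 in the lower molar, and collagens 0.01 and 0.13. Mcm2 to Mcm7, also among the proliferation genes, had medians of -0.05 and -0.31. In each of these families limma called 0 genes, with 1 of 20, 9 of 21 and 0 of 6 at an unadjusted p under 0.05. Of 77 ribosomal protein genes, 70 were higher in the mutant in both molars, with medians of 0.22 in the upper and 0.19 in the lower molar (0.20 and 0.25 after rescaling). limma called 0 of them, with 30 at an unadjusted p under 0.05, against 1386 of all 10502 tested genes. Of 61 histone genes, 55 were lower in the mutant lower molar, with a median of -0.41 (-0.36 after rescaling), against -0.03 in the upper molar (-0.06 after rescaling). limma called 0 of the histone genes, with 17 at an unadjusted p under 0.05. The difference between molars was not tested.

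Of the 36 genes called higher in the mutant, 8 were also called higher in the lower molar, where independent lists would share 0.14: Chodl, Ddah1, Fgf18, Lrrn1, Lrrtm1, Nbl1, Osr1 and Tbx15. Of the 36, 1 was called lower in the lower molar, against 0.12. Of the 48 genes called lower in the mutant, 0 were called in either direction between molars by limma. Both calls use the same residual of each gene, which favours shared calls in every direction. Across the 10502 genes the mean genotype difference and the mean molar difference correlated with r = 0.16. Ddah1, Lrrtm1 and Tbx15 were named after their values were seen.

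The highest FPKM in the tables belonged to Lars2, between 5004 and 6271, and Mtrnr2l, between 4631 and 5028. Lars2 was higher in the mutant by 0.22 in the upper and 0.20 in the lower molar, and Mtrnr2l had differences of 0.03 and -0.12.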
